A study of Homo sapiens with 6 samples.

How the data were processed

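Gene expression was measured in 6 clones of KYSE150, an established human oesophageal squamous cell carcinoma line. Per the labels, 3 clones (1, 4 and 5) carried the empty pIRES2-EGFP vector and are called mock, and 3 clones (1, 6 and 17) were stably transfected with NCCRP1. Each clone gave 1 library. Per the labels' protocols, total RNA was treated with DNase, depleted of ribosomal RNA and made into libraries for the Ion Torrent platform. Mock clones 1 and 4 and NCCRP1 clone 1 were read in sequencing run 15, and mock clone 5 and NCCRP1 clones 6 and 17 in run 14, as named in the deposited data.

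The submitters' processing notes name the hg19 genome build and bedtools 2.25.0, without their roles; the aligner was not given in the sources used here. Per the file headers, the authors deposited 1 RPKM value for each of 40448 Entrez gene IDs in each library. The deposited values were in fact log2 RPKM: 2 to the power of the value, times exonic length in kilobases and summed over genes, came to 1090000 to 1100000 in each library, whereas natural logarithms would give at least 11000000. No value lay below 0, so genes under 1 RPKM were listed as 0. Some genes that every cell uses, such as TPT1 and UBB, were listed at 0 in all 6 libraries, so a 0 also stood for genes without an estimate. A 0 is therefore given only as a listed value, and no fold change is given for a gene listed at 0 in any library.

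Depth was read from the microRNA genes, whose low values rose in whole-read steps. The best-fitting step within a preset range put the reads behind the RPKM denominator at 12290000, 12690000 and 15960000 in mock clones 1, 4 and 5. In NCCRP1 clones 1, 6 and 17 it put them at 18080000, 15860000 and 14570000. Whole multiples or whole fractions of these depths lay outside the range searched and are not excluded. Of the microRNA values under 8 steps, 24.1% to 33.8% per library lay within 0.005 of a whole step. By chance 1% would, for a step that was not chosen to fit. Too few were whole to recover counts for all genes, so no count model was run.

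The log2 RPKM values were compared as deposited with limma 3.58.1 in R 4.3.3 (trended and robust empirical Bayes, group as the sole term, two-sided). Genes listed above 0 in at least 3 of the 6 libraries were tested, 12737 in all, with Benjamini-Hochberg adjustment and a threshold of 0.05. The plan made before the data were examined was a count model, with limma on log2(value + 1) for normalized values. Since the files already held logarithms, no pseudocount was added, and log2(RPKM + 1) became an alternative. The 36 gene lists, the rule for named genes and the other settings compared were also fixed before the data were examined, with exceptions. Settings on GC trends, neighbouring genes, a listed 0 as missing, a mean log2 of at least 1 and the F-box-associated list without NCCRP1 were added after seeing the data.

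Lists with at least 5 tested members were compared with the other genes by camera with an inter-gene correlation preset at 0.01. Camera with an estimated correlation and fry gave further values. Each list member was also adjusted over the list alone. The named genes were NCCRP1, then up to 12 genes per direction that passed the test with no overlap between groups. Where fewer than 12 passed, the rest were those with the lowest unadjusted p. From each list, up to 4 members with the lowest p were named, and some of these are not reported here. The symbols of 37997 gene IDs came from the RefSeq annotation of GRCh38.p14, which also gave the order of neighbouring genes. No coordinates are given, because that build differs from hg19.

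GC content was taken from the longest GENCODE v29 transcript of each gene and was available for 94.0% of tested genes. In an added correction, a loess trend of each library's deviations with GC content (span 0.5) was removed. To look for shifts of neighbouring genes, 8559 protein-coding genes with a mean log2 RPKM of at least 2 and a value above 0 in every library were put in chromosome order. Medians were taken over windows of 30 genes in steps of 15 and compared with the highest window of 100 shuffled orders. A second added correction subtracted from each gene the median deviation of its 30 nearest neighbours in the same library. Both corrections left a listed 0 unchanged, so a gene listed at 0 in some libraries was corrected only in the others.

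The gene test was tested on simulated values for the same 12737 genes, with real means and spreads, a floor at 0 and 200 changed genes. The 200 changed genes were drawn from those with a mean log2 RPKM of at least 2, and noise was independent between genes. Other members of the NF-kB list were also shifted by a log2 of 0.5 and counted neither as changed nor as unchanged. Shifts shared between genes, by run, GC content or block, were not simulated. The rates below therefore do not describe genes of lower mean or such shifts. The test recovered 3 of 50 genes changed by a log2 of 0.5, 28 of 50 at 1, 42 of 50 at 1.5 and 48 of 50 at 2. It made 4 calls among unchanged genes and none when no gene was changed. In the real data the median standard error of a log2 difference was 0.19, which gives a 95% interval of about 0.419 on either side. The clones share only clone number 1 between groups, so no pairing was used. Alternatives covered the centring of the libraries, the filter, the empirical Bayes setting, the run, the pseudocount and leaving out each clone. Lists of fibroblast, leukocyte, endothelial and glandular markers had under 5 tested members, and mitochondrially encoded transcripts matched no gene ID and were not analysed here.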

Results

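Transcriptomes of 6 stably transfected KYSE150 clones were compared to ask which genes differ when NCCRP1, which encodes a protein with an F-box-associated domain, is expressed in an oesophageal squamous carcinoma line. Libraries from 3 mock and 3 NCCRP1 clones held 12477 to 12821 genes above 0, at 12290000 to 18080000 reads as estimated from the microRNA steps. Libraries correlated across genes with r between 0.971 and 0.990, and none of the 11927 genes above 0 in every library had an equal value in any pair of libraries. The clones were separately labelled, but p-values measure only the spread between these 6 libraries. Squamous and housekeeping control genes differed between the groups by less than the larger SD of the clones. Log2 RPKM was 10.93 ± 0.04 in mock and 10.98 ± 0.14 in NCCRP1 clones for GAPDH, and 8.69 ± 0.18 and 8.86 ± 0.10 for ACTB (SD, n = 3 each). KRT5 stood at 10.17 ± 0.20 and 10.21 ± 0.66, EGFR at 5.44 ± 0.08 and 5.48 ± 0.08, and TP63 at 4.43 ± 0.46 and 4.07 ± 0.19.

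NCCRP1 itself (Entrez 342897) was listed at 0 in all 3 mock clones and at log2 RPKM 6.19, 8.07 and 6.71 in NCCRP1 clones 1, 6 and 17, which is 72.8, 269 and 105 RPKM. The gene passed limma's test (adjusted p = 0.00449), but not without mock clone 1, 4 or 5 (limma adjusted p of 0.0626, 0.0507 and 0.0549). The mock values are all the listed 0 and have no spread, whereas the NCCRP1 clones had an SD of 0.97. Leaving out a mock clone therefore left the difference of the listed values at 6.99, and these p-values do not show a dependence on particular mock clones. The exact permutation test of the 3 against 3 values gave p = 0.1, the smallest two-sided value that this design allows.

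Beyond NCCRP1, 8 genes rose and 4 genes fell in the NCCRP1 clones. The genes that rose and were above 0 in every library were GADD45B, a stress-induced regulator of growth arrest, CCN1, a matricellular protein and YAP target, NUPR1, a stress-induced nuclear protein, EDN1, the endothelin 1 precursor, and the secreted protein gene CCDC80. GADD45B went from 4.30 ± 0.39 to 5.89 ± 0.16 (SD, n = 3 each), a 3.02-fold rise (log2 difference 1.59, SE 0.19, limma adjusted p = 0.0154). CCN1 rose 2.65-fold (1.41, SE 0.22, limma adjusted p = 0.0447), NUPR1 2.58-fold (1.37, SE 0.20, limma adjusted p = 0.038), EDN1 2.54-fold (1.34, SE 0.20, limma adjusted p = 0.038) and CCDC80 2.15-fold (SE 0.17, limma adjusted p = 0.0447). Among the genes that fell, KLK6, a secreted serine protease of the kallikrein family, went from 4.72 ± 0.16 to 3.14 ± 0.37, or 0.335 times the mock level (limma adjusted p = 0.0154). CTXN1, encoding cortexin 1, went from 3.10 ± 0.09 to 1.86 ± 0.24, or 0.424 times (limma adjusted p = 0.0388).

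The other genes that passed were listed at 0 in at least 1 library. KLK8, a kallikrein expressed in squamous epithelia, was at 1.66, 1.63 and 2.18 in mock clones 1, 4 and 5 and listed at 0 in every NCCRP1 clone (limma adjusted p = 0.0154). Because the listed 0 of the NCCRP1 clones has no spread, this p-value may be too low. NPDC1 was at 2.71, 2.91 and 2.72 in the mock clones against 0, 0 and 0.98 in NCCRP1 clones 1, 6 and 17 (limma adjusted p = 0.0154). SAA2-SAA4, a read-through of the acute-phase serum amyloid A genes, was at 0, 0.92 and 0 in the mock clones and 2.08, 3.30 and 2.74 in the NCCRP1 clones (limma adjusted p = 0.038). It shares sequence with SAA2 and SAA1 and its value is uncertain for that reason. The small RNA genes MIR224 (0, 0.39 and 0 against 1.86, 1.66 and 2.55) and SNORD114-3 (0.14, 0 and 0 against 2.17, 1.35 and 2.48) lie in host transcripts or clusters whose reads could be shared, and both passed at a limma adjusted p of 0.038.

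**Figure D1:**
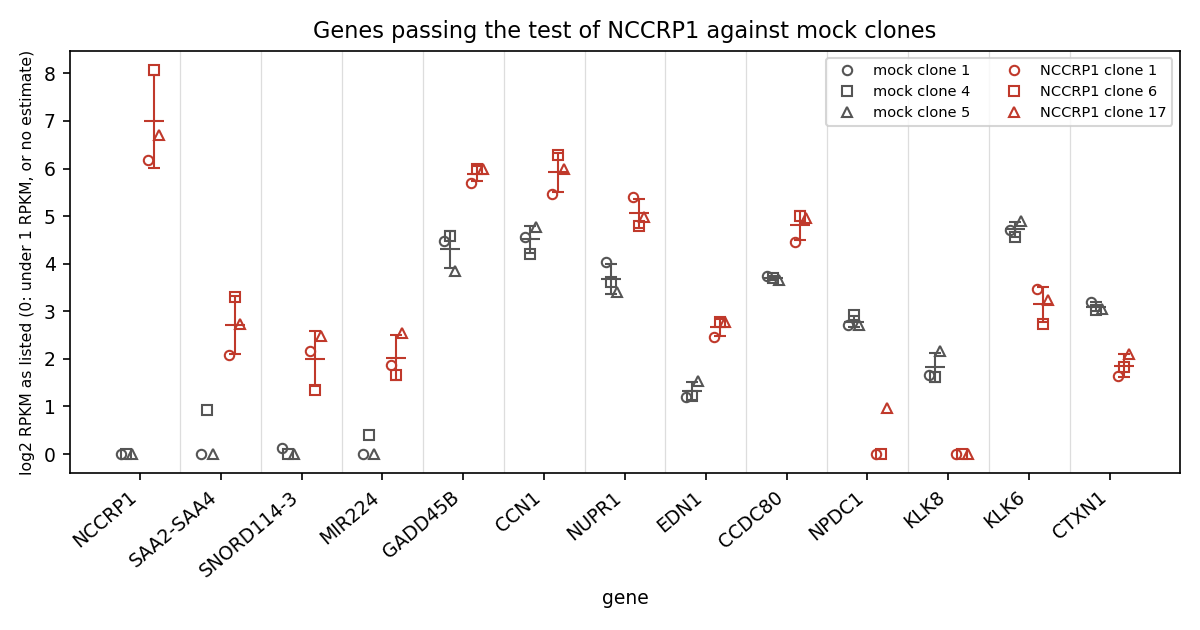
Log2 RPKM of the 13 genes that passed limma's test, for each of the 3 mock (grey) and 3 NCCRP1 (red) clones; bars give the mean ± SD of groups in which no library is listed at 0. In each gene all NCCRP1 clones lie on one side of all mock clones, from 0 against 6.19 to 8.07 for NCCRP1 to 3.03 to 3.20 against 1.64 to 2.11 for CTXN1.

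The rest of the up to 12 named genes per direction missed the threshold. Upward these were PDZK1IP1, MIR5087 and the chemokine gene CXCL2, at limma adjusted p of 0.0521, 0.0535 and 0.0599. CXCL2 stood at 2.83 ± 0.24 in mock and 4.08 ± 0.35 in NCCRP1 clones. Downward, the endocytic collagen receptor gene MRC2 (4.77 ± 0.19 and 3.60 ± 0.33), the transporter gene SLC47A2 (1.77 ± 0.33 and 0.31 ± 0.27) and PLEKHG4 (2.89 ± 0.08 and 1.60 ± 0.40) had limma adjusted p of 0.0535, 0.0661 and 0.0707. MATCAP1, the differentiation-linked TINCR, the Hedgehog pathway transcription factor gene GLI1, ELAPOR2 and GRTP1 had log2 differences of -0.986, -0.997, -1.12, -1.55 and -0.863, at limma adjusted p from 0.0759 to 0.109.

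With the run as a term in limma, 2 of the 13 passed (NCCRP1 and NUPR1); without mock clone 5 no gene passed, with 1363 at an unadjusted p under 0.05, and the other clones left out gave 2 to 29 genes. Other settings also ended most of the calls: 3 genes passed with no filter, 5 with robust=FALSE, 4 with log2(RPKM + 1), 1 with log2(RPKM + 0.1) and 4 with the GC trend removed. With a listed 0 as missing 2 passed, but only 7 of the 13 then had a value to test. In all, 934 genes had an unadjusted p under 0.05, against 637 by chance, and 12.8% of genes had groups that did not overlap, against 10% by chance.

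Of 31 gene lists, 12 were higher and 3 lower in the NCCRP1 clones than other genes by camera with the preset correlation. None of the 15 passed with an estimated correlation, where their adjusted p ran from 0.334 to 0.767. By fry, 0 of the 31 lists passed the directional test (NF-kB cytokines and chemokines at adjusted p = 0.179) and 8 passed the test for changes in either direction. All 14 tested NF-kB cytokines and chemokines had a higher mean in the NCCRP1 clones, with a median log2 difference of 1.01 (camera adjusted p = 3.37e-15; adjusted p = 0.334 with an estimated correlation). Adjusted over the list alone, 10 members rose; none passed over all genes. The interleukin gene IL6 went from 2.98 ± 0.67 to 4.92 ± 0.29 (SD, n = 3 each) and IL1B from 2.16 ± 0.53 to 3.28 ± 0.22, at limma adjusted p of 0.00084 and 0.00427 over the list alone. TNFAIP3, which encodes a feedback inhibitor of NF-kB, went from 2.30 ± 0.63 to 3.49 ± 0.09. The list's mean over its members was 0.785 higher in NCCRP1 clones within run 15 and 1.29 higher within run 14.

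The YAP target list had 13 of 15 members higher (median 0.301, camera adjusted p = 2.61e-06; adjusted p = 0.334 with an estimated correlation). CCN1 passed over all genes, and 6 members rose adjusted over the list alone, among them the kinase gene NUAK2 (2.84 ± 0.49 and 3.90 ± 0.34) and tissue factor, F3 (4.30 ± 0.41 and 5.51 ± 0.72). The list's mean difference was 0.148 within run 15 and 0.687 within run 14. CCN2 was listed at 0 in the mock clones and at 0.67, 0.60 and 1.42 in the NCCRP1 clones. In the TGF-beta and BMP target list, 10 of 15 members had a higher mean and 5 a lower one (median 0.31, camera adjusted p = 3.26e-05; adjusted p = 0.334 with an estimated correlation), and 5 members rose over the list alone. TGFB2, a TGF-beta ligand gene, went from 3.98 ± 0.38 to 5.02 ± 0.55. Within run 15 this list's mean difference was 0.0793, against 0.586 within run 14, and its library means overlapped between the groups.

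Interferon-stimulated genes had list means of -0.262, 0.329 and 0.799 in NCCRP1 clones 1, 6 and 17, against -0.384, -0.136 and -0.345 in mock clones 1, 4 and 5, relative to each gene's mean. The list's median difference was 0.369 over 23 members (camera adjusted p = 7.01e-10; adjusted p = 0.334 with an estimated correlation), and 3 members, RSAD2, OAS1 and IFIT3, rose over the list alone. IFIT3 was at 2.09, 2.38 and 2.28 in the mock clones and 2.62, 3.78 and 4.21 in NCCRP1 clones 1, 6 and 17. The list's mean difference was -0.00182 within run 15 and 0.909 within run 14. Cholesterol synthesis genes had 20 of 22 members higher (median 0.169, camera adjusted p = 2.68e-05; adjusted p = 0.334 with an estimated correlation), and INSIG1, a brake on sterol synthesis, rose over the list alone from 2.56 ± 0.14 to 3.38 ± 0.20.

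Replication-dependent histone genes, whose transcripts mostly lack poly(A) tails, were lower in the NCCRP1 clones, in 26 of 28 members (median -0.434, camera adjusted p = 2.32e-10; adjusted p = 0.334 with an estimated correlation). Without NCCRP1 clone 1 the median was -0.268. Over the list alone 4 fell, and H4C1 was at 8.98 ± 0.13 in mock and 8.15 ± 0.26 in NCCRP1 clones. Members have near-identical copies, so single histone genes are uncertain. The library means were 0.404, 0.0566 and 0.198 in mock clones 1, 4 and 5 and -0.605, 0.0238 and -0.0777 in NCCRP1 clones 1, 6 and 17, relative to each gene's mean, a difference of -0.836 within run 15 and -0.225 within run 14. Genes of G1/S and DNA replication were also lower (21 of 25 members, median -0.143, camera adjusted p = 0.0103; adjusted p = 0.665 with an estimated correlation), with no member passing over the list alone. Library means of this list overlapped: 0.126, 0.0403 and 0.061 in mock clones 1, 4 and 5 and -0.222, 0.221 and -0.226 in NCCRP1 clones 1, 6 and 17, so clone 6 was the highest of all. The member with the lowest p went the other way: the cyclin D1 gene CCND1 stood at 4.93 ± 0.05 in mock and 5.52 ± 0.41 in NCCRP1 clones. MCM4 and MCM3, subunits of the replicative helicase, had log2 differences of -0.36 and -0.49. Genes of G2/M and mitosis did not pass (camera adjusted p = 0.341).

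**Figure D2:**
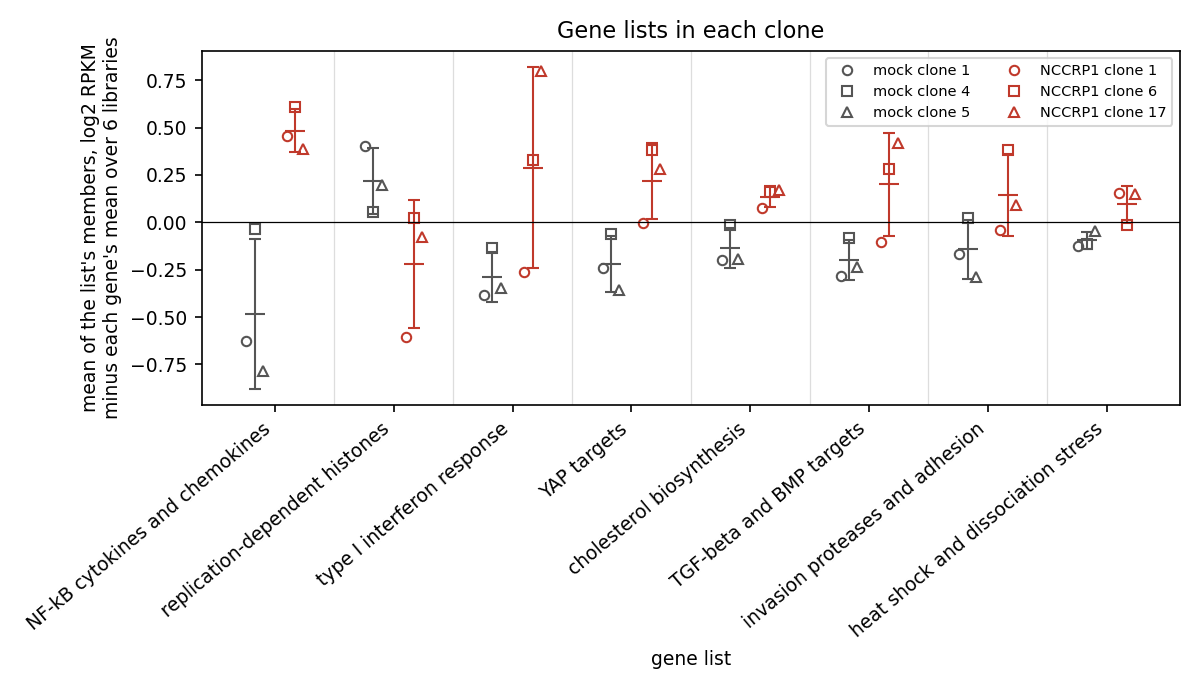
Mean of each list's members in each clone, as log2 RPKM minus each gene's mean over the 6 libraries, for the 8 lists with the lowest camera p; bars give the mean ± SD of 3 clones. All NCCRP1 clones lie above the mock clones for NF-kB cytokines (0.388 to 0.610 against -0.787 to -0.038) and below them for histones, while the interferon means overlap (-0.262 in NCCRP1 clone 1).

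Invasion proteases and adhesion genes moved both ways: 3 members, among them ITGB6 and CTSB, rose over the list alone while KLK6 fell (median 0.329, camera adjusted p = 0.000806; adjusted p = 0.334 with an estimated correlation). The list's mean difference was 0.0291 within run 15 and 0.523 within run 14, and its library means overlapped between the groups. The cathepsin gene CTSB stood at 5.59 ± 0.22 in mock and 6.07 ± 0.12 in NCCRP1 clones. In the immediate early list, IER3 rose over the list alone from 5.22 ± 0.07 to 5.84 ± 0.08 (list median 0.0418, camera adjusted p = 0.0239; adjusted p = 0.334 with an estimated correlation), but the list's median was -0.0226 without mock clone 4. Heat shock genes (median 0.167) and apoptosis regulators (0.104) had camera adjusted p of 0.00185 and 0.00424, and an adjusted p of 0.334 with an estimated correlation. No member of either list passed on its own, including HSPA1A and PMAIP1. Oxidative phosphorylation genes such as UQCRC2 (list median 0.0994) and amino acid response genes such as GPT2 (-0.148) passed camera at adjusted p of 0.045 and 0.0345, both with an adjusted p of 0.421 with an estimated correlation, and no member passed.

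Cytosolic ribosomal protein genes were higher in 27 of 30 members (median 0.127, camera adjusted p = 0.00607; adjusted p = 0.767 with an estimated correlation), but the median was -0.0748 without mock clone 5 and -0.00292 without NCCRP1 clone 1. Mock clone 5 had the lowest mean of this list, -0.429. The F-box-associated list owed its camera adjusted p of 0.0183 (adjusted p = 0.334 with an estimated correlation) to NCCRP1: without that gene the adjusted p was 0.699, and without mock clone 5 the median turned from 0.131 to -0.0287. The related FBXO27, FBXO44 and FBXO6 had log2 differences of -0.26, 0.18 and 0.15.

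Lists that did not pass camera included squamous terminal differentiation (adjusted p = 0.798), in which S100A8 rose and the transglutaminase gene TGM1 fell over the list alone. Of this list's 34 matched members 15 were tested, and 18 were listed at 0 in all libraries. TGM1 was at 3.72 ± 0.35 and 2.86 ± 0.20. Notch and Wnt targets also missed (adjusted p = 0.0674), with NOTCH3 (5.27 ± 0.27 and 4.59 ± 0.04) and TCF7 falling over the list alone. In the mesenchymal list (adjusted p = 0.24), 2 members, among them the integrin gene ITGA5, rose and S100A4 fell over the list alone. Basal squamous identity genes (adjusted p = 0.302) passed for no member. The library means of this list did not overlap, at 0.0612 to 0.156 in mock and -0.262 to 0.05 in NCCRP1 clones, relative to each gene's mean. Such a separation was seen for 10 of the 31 lists, against 3.1 by chance. KRT15 was at 8.16 ± 0.64 in mock and 6.74 ± 0.85 in NCCRP1 clones, and KRT14 at 3.31 ± 1.17 and 1.74 ± 0.58. Epithelial junctions, p53 targets, autophagy and lysosome, antigen presentation, hypoxia and glycolysis, fatty acid metabolism, NRF2 targets, MYC and ribosome biogenesis, the unfolded protein response, SCF ubiquitin ligase subunits and small noncoding RNAs had camera adjusted p from 0.181 to 0.94. No member of these lists rose or fell over its list alone. Fry's test for changes in either direction was passed by squamous terminal differentiation and by Notch and Wnt targets (fry adjusted p of 0.00168 and 0.00181). Fatty acid metabolism passed it too (fry adjusted p = 0.033).

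Of the markers of other cell types, COL1A1 lay between 1.32 and 2.57 and ENG between 2.87 and 3.46 over the 6 libraries. COL6A1 lay between 0.07 and 1.38 and FBLN1 between 3.01 and 3.63. CSF1R was lower in every NCCRP1 clone (1.99 to 2.06) than in any mock clone (2.12 to 2.43). CD68 was at 5.09 to 5.94. The simple-epithelial keratin genes KRT7, KRT8 and KRT18 had higher values in every NCCRP1 clone than in any mock clone, without passing (limma adjusted p of 0.716, 0.662 and 0.341). KRT7 was at 3.36 ± 0.96 in mock and 4.52 ± 0.59 in NCCRP1 clones, KRT8 at 7.84 ± 0.19 and 8.24 ± 0.13, and KRT18 at 7.63 ± 0.15 and 8.31 ± 0.26. MUC1, of the same list, had a lower mean in the NCCRP1 clones with overlap (1.81 ± 0.50 and 1.53 ± 0.89).

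GADD45B lies among the first genes of chromosome 19 in RefSeq order, and its neighbours were also higher in the NCCRP1 clones. The stretch from PLPP2 to ZBTB7A was picked after seeing the data. With the GC trend removed, a stretch with exactly these ends lay beyond the shuffled orders in 5 libraries, the most of any stretch. In NCCRP1 clone 6 a longer stretch did, from PLPP2 to DPP9. The stretch from PLPP2 to ZBTB7A thus lay beyond the shuffled orders in every library. Of its 75 expressed genes, 73 had a higher mean in NCCRP1 clones, with a median log2 difference of 0.531 (quartiles 0.414 and 0.619). The groups did not overlap for 74.7% of them, and GADD45B alone passed limma's test. Among these neighbours APBA3, GNA15 and RPS15 had log2 differences of 0.98, 0.89 and 0.78; they were chosen after their values were seen. After its neighbours' shift of 0.431 was subtracted, GADD45B's difference was 1.16. CTXN1, which passed limma's test and also lies on chromosome 19, had a neighbour shift of -0.137. After this was subtracted its difference was -1.10, and it no longer passed. Some named genes that missed the threshold also lie among shifted neighbours: GRTP1 on chromosome 13 (neighbour shift -0.345), MATCAP1 and PLEKHG4 on chromosome 16 (-0.276 for both) and TINCR on chromosome 19 (-0.21).

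**Figure D3:**
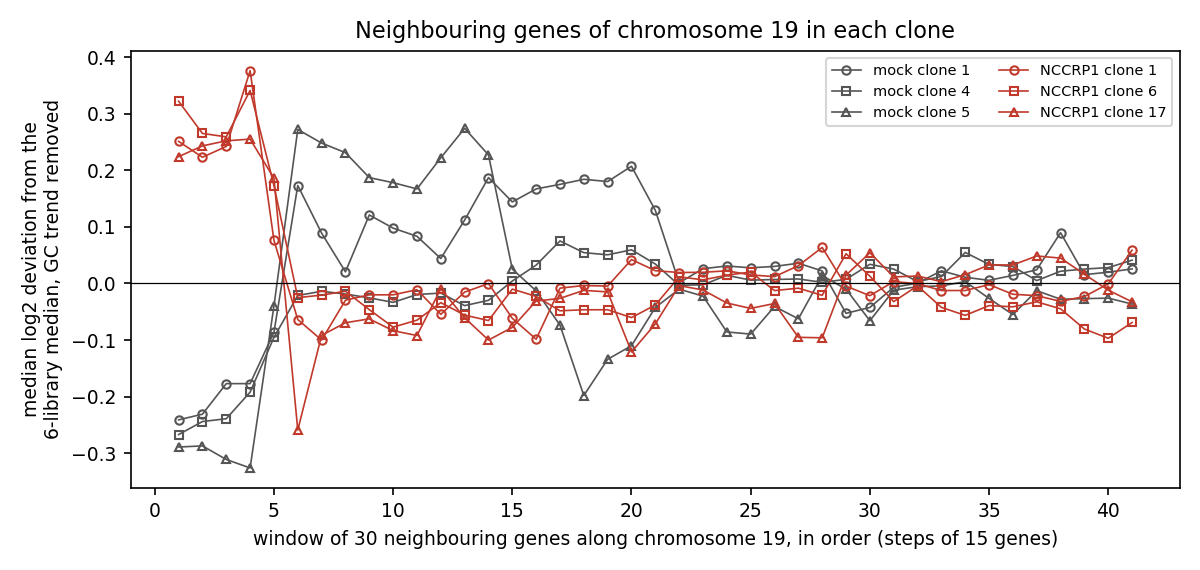
Median log2 deviation of 30 neighbouring genes from the 6-library median, with each library's GC trend removed, in windows along chromosome 19 in gene order for 3 mock (grey) and 3 NCCRP1 (red) clones. The first windows separate the groups; over the 75 genes from PLPP2 to ZBTB7A the medians were -0.295 to -0.213 in mock and 0.244 to 0.307 in NCCRP1 clones.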

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

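The settings that subtract GC trends or neighbours, treat a listed 0 as missing or ask for a mean log2 of at least 1 were chosen after seeing the data. So was the F-box-associated list without NCCRP1. The others were planned. Under median-ratio or upper-quartile centring and totals without small RNA genes, 11 to 14 genes passed limma's test against 13 as reported; 9 did with neighbouring genes subtracted and 16 with a mean log2 of at least 1, all within 1.5 times. Fewer genes passed with no filter (3: 1 higher, 2 lower), robust=FALSE (5, with 2 higher), the run as a term (2 higher, 0 lower), log2(RPKM + 1) (4: 2 and 2), log2(RPKM + 0.1) (1 higher, 0 lower), a listed 0 as missing (2: 1 and 1) and the GC trend removed (4: 3 and 1). With a listed 0 as missing, only 7 of the 13 reported genes had a value to test. A threshold of 0.1 gave 27, 18 higher and 9 lower. Leaving out each clone in turn gave 0 to 29 genes (0 to 24 higher, 0 to 5 lower), with 0 without mock clone 5 and 29 without NCCRP1 clone 1. The cause of these moves was not tested. Leaving out a clone also leaves fewer libraries in the fit. Without mock clone 5 the mock clones are all from run 15, and without NCCRP1 clone 1 the NCCRP1 clones are all from run 14. In these fits the group is partly mixed with the run. None of the named genes changed direction under any setting run. With a clone left out, NCCRP1's listed values minus the listed 0 of the mock clones averaged 6.45 to 7.39, from which no fold is drawn; without mock clone 1, 4 or 5 they averaged 6.99 at limma adjusted p of 0.0626, 0.0507 and 0.0549. Between 11 and 16 lists passed camera with a clone left out and 13 to 15 under the other settings, but 0 with an estimated correlation. The NF-kB median stayed between 0.851 and 1.23 and the histone median between -0.552 and -0.268 in the settings with a preset correlation. With a clone left out, medians ran from -0.0748 to 0.272 for ribosomal proteins, -0.0287 to 0.26 for the F-box-associated list and -0.0226 to 0.114 for immediate early genes, so these directions rest on single clones. Count-based tests (DESeq2, edgeR, voom) were not run, since counts could not be recovered, and library-size scaling and a minimum of 1 in 3 libraries coincide with the reported settings. No paired analysis was possible because the groups share only clone number 1. Of the 13 genes, 6 were listed at 0 in at least 1 library; the effect of depth on them was not tested.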

Other observations

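The tests on GC content and neighbouring genes for the NF-kB list, on the histone neighbours, on the splits for lists and on GC content for all blocks together were set before their results were seen, and the other tests after. All 5 kallikrein genes tested had a lower mean in the NCCRP1 clones with no overlap between the groups. KLK6 and KLK8 passed limma's test; KLK5, KLK9 and KLK10 did not (limma adjusted p of 0.461, 0.412 and 0.415), and no test was run on the family. KLK5, which encodes an epidermal protease, was at 7.39 ± 0.09 in mock and 6.75 ± 0.44 in NCCRP1 clones, and KLK10 at 4.01 ± 0.14 and 3.38 ± 0.39 (SD, n = 3 each). The acute-phase genes SAA1 and SAA2 lay on the other side with SAA2-SAA4. SAA1 was at 2.80, 3.504 and 0.574 in mock clones 1, 4 and 5 and 4.88, 5.89 and 4.97 in NCCRP1 clones 1, 6 and 17, without passing (limma adjusted p = 0.518). Both families were looked at after KLK6 and SAA2-SAA4 had been seen to pass.

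Single clones also carried their own shifts of neighbouring genes. In NCCRP1 clone 6, 255 genes of chromosome 10 from SVIL to ZNF511 had a median log2 deviation of -0.503 after the GC trend was removed, against 0.0105 to 0.0511 in the other libraries. In NCCRP1 clone 1, genes from PIGG to NOA1 on chromosome 4 (-0.45) and from EXOSC3 to ENTPD8 on chromosome 9 (-0.324) were lower. In NCCRP1 clone 17 the same held from ZC3HC1 to CHPF2 on chromosome 7 (-0.424) and over 180 genes from ARMC5 to ZCCHC14 on chromosome 16 (-0.425, against -0.022 to 0.15 in the other libraries). Mock clone 5 was higher from ANXA5 to UFSP2 on chromosome 4 (0.447), and mock clone 4 was lower from C11orf68 to CLPB on chromosome 11 (-0.352). Some windows also separated the groups. On chromosome 13 the window from MBNL2 to GRTP1 had medians of 0.184 to 0.198 in mock and -0.202 to -0.143 in NCCRP1 clones. At the start of the chromosome 16 stretch the window from ARMC5 to BBS2 had 0.113 to 0.211 and -0.51 to -0.059, with clone 17 the lowest. The groups did not overlap in 98 of 535 windows, against 19 to 85 in the other splits, the real split being 1 of 10. A few genes stood apart in single libraries: C19orf33 was listed at 4.00 in mock clone 5 and at 0 elsewhere, and the imprinted PLAGL1 was at 3.27 in mock clone 1 and 3.22 in NCCRP1 clone 17 but at most 0.83 in the other libraries.

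Of the 10 splits of the 6 libraries into 3 and 3, the real split, 1 of 10, gave the highest counts, 13 genes and 15 lists. The other splits gave at most 0 genes by limma, with 210 to 1550 at an unadjusted p under 0.05, and at most 12 lists. With 10 splits no share can fall under 0.05. The split by sequencing run had the 1550 genes, more than the 934 of the real split. Deviations from the 6-library median correlated across genes with GC content, at Spearman's rho of 0.515, 0.404 and 0.107 in the libraries of run 15 (mock clones 1 and 4, NCCRP1 clone 1) and -0.63, -0.295 and -0.0633 in those of run 14 (mock clone 5, NCCRP1 clones 6 and 17). Genes are not independent replicates in these values.

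Technical explanations were weighed for the rise of NF-kB cytokines and chemokines. The list's mean difference was 0.816 without mock clone 5 and 1.04 (SE 0.265) with the run as a term, which argues against that clone or the run as the whole cause. Its median was 0.983 with the GC trend removed and 1.01 with neighbouring genes subtracted, against 1.01 before, which argues against GC content and chromosome blocks. An effect of NCCRP1 may account for the rise, as a hypothesis. It stays open, because clones that came from 1 parent line can differ in cytokine level before transfection and no such clones were compared.

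For the lower histone transcripts, a shift of the whole histone gene block was tested on the 12 non-histone genes between the histone genes of chromosome 6. Their median difference was -0.0261 against -0.434 for the histones (SE 0.0643 over these genes, not over libraries). The library means of these neighbours overlapped between the groups. They were -0.12, -0.023 and 0.117 in mock clones 1, 4 and 5 and -0.154, 0.0709 and 0.109 in NCCRP1 clones 1, 6 and 17. This argues against a block shift as large as the histones' fall, but the spread leaves a smaller shift open. Without NCCRP1 clone 1 the list's mean difference was -0.247 against -0.439 with it, so the share of that clone stays open. Fewer cells in S phase could also lower histone transcripts; the G1/S list differed by -0.151 (SE 0.151), too wide a spread to decide.

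The blocks of neighbouring genes were not explained by a chance order of genes, since 154 windows over the 6 libraries exceeded the highest of 100 shuffled orders. With the GC trend removed, 71.4% of these windows remained, 93.8% in the NCCRP1 clones and 47.3% in the mock clones. In the mock clones 57 windows then exceeded the shuffled orders (21, 17 and 19 in clones 1, 4 and 5), against 74 before. This argues against GC content as the whole cause in either group; its part in the 39 mock windows that were lost stays open. The block at the start of chromosome 19 kept a difference of 0.522 (SE 0.0304) after the GC correction and of 0.568 (SE 0.123) with the run as a term. The block was picked from the GC-corrected values, so the first of these differences cannot decide on GC content. Its window difference of 0.556 compared with at most 0.315 in the other splits, the real split being 1 of 10. Differences in gene copy number between clones, and a shared origin of the clones within a group, are a candidate explanation that RNA cannot settle. NCCRP1 lies on the same chromosome, outside the block. The neighbours of its own locus had a mean deviation of -0.0219 in the NCCRP1 clones. None was taken for the mock clones, where NCCRP1 is listed at 0, so no group difference is given.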
